A study of Mus musculus with 2 samples.

How the data were processed

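Poly(A) RNA of the heart of 1 female adult C57BL/6J mouse aged 10 weeks was sequenced in 2 libraries, technical replicates 1 and 2 of 1 biological replicate, per the labels. RNA was extracted with a kit for lipid-rich tissue and the size range is given as 350 to 450, per the labels. Replicate 2 was made in 2015, after the publication that used replicate 1, per the labels. There is 1 animal and no group to compare, so a spread over the 2 libraries is technical, and no statement here extends to other mice.

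The deposited tables list genes and transcripts of mouse assembly mm10 with annotation release M4, per the deposited file descriptions; the aligner and the program that estimated abundances are not given in the sources used here. Expected counts, which need not be whole, are in the deposited tables per gene and per transcript. TPM, an abundance corrected for transcript length, is scaled to a fixed sum per library in the deposited tables, so a gene's TPM falls when other RNAs take a larger share. FPKM values are given beside them in the deposited tables. The share of a gene's abundance carried by each transcript is a percent in the deposited transcript tables. Posterior means and SDs of the counts and interval bounds are also deposited; the posterior values served only in alternatives, and the interval bounds, whose level is not stated, were not used. Whether counting used strand is not given in the sources used here, so reads of overlapping antisense genes cannot be separated.

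The gene tables list 69691 features. Counts were found in none of the 96 spike-in features, the 1 phiX feature or the 26248 features with a numeric identifier, and the 43346 Ensembl genes held all counts. Identifiers were matched without their version to release M21 of the same assembly (GRCm38 is mm10), which gave 42462 genes a symbol. Coordinates are those of release M21 and are 1-based. GC content per gene is the mean over its M21 transcripts weighted by TPM, and 99.8% of the 13182 tested genes had a value. Nuclear genes were compared with mitochondrial genes by blastn 2.17.0, and 10 with at least 95% identity over at least 90% of their length were treated as copies whose reads are uncertain.

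Totals were 22775979 counts in replicate 1 and 19685806 in replicate 2. Expected counts were rounded to whole numbers for tests. Levels are TPM in each library. Ratios of 35 gene pairs are log2 of (TPM + 0.1), with ratios of counts per effective length, from the deposited tables, where a gene had 3 counts or fewer in a library, a step chosen after seeing the data. Correlations use log2(TPM + 1) over genes with a mean TPM of at least 1. For each gene with at least 20 counts over both libraries, a two-sided exact binomial test in edgeR 4.0.16 (R 4.3.3), with a chi-square approximation for very large totals, compared the libraries. Library sizes were TMM-scaled, and the log2 ratio (replicate 2 over replicate 1) had 0.5 counts added. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. These tests compare those libraries, not conditions, and cover counting error only, since reads are not independent molecules. Intervals for shares are 95% Wilson intervals, those for single ratios are exact binomial, and a count of 0 allows up to 3 counts.

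A median log2 ratio was set against 10000 random lists of the same size, matched on mean TPM in 20 bins, for each fixed list with at least 5 tested genes. The percentile describes these libraries and is no test. Statistics used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The trend with GC content was removed as the median log2 ratio in 50 bins of GC content, a step chosen after seeing the data. For pair ratios and correlations it was applied to replicate 1, which brings that library to the GC profile of replicate 2.

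The calling step was tested on simulated counts for the real genes and library sizes, drawn with counting error only. Of 50 genes changed 1.5-fold none passed, as the 2-fold threshold requires, and 88% of those changed 2.5-fold, 92% of those changed 4-fold and 92% of those changed 8-fold were called, with 2 false calls among 13036 genes. With a GC trend added and then removed, these shares were 78%, 94% and 92%, with 43 false calls among 12903 genes. The real libraries differed far beyond counting error, so these shares and false calls do not carry over to them.

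Lists, gene pairs, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 20 genes of highest mean TPM, the 4 members of highest mean TPM per list with members at 0 where absence is reported, both genes of every pair, the 10 called genes with the largest ratio in each direction at a mean TPM of at least 1, and the isoform genes with their 2 leading transcripts. The values of 1 pair and of 1 marker gene that the rule takes are not reported here. Alternatives covered scaling, filters, pseudocounts, the abundance estimate, the error model and leaving out a library. Gene lists cover the sarcomere, calcium handling, channels, fatty acid oxidation, glycolysis, the respiratory chain, ribosomal proteins, transcription factors, chambers, other cell types of the heart and neighbouring tissues, sex genes, stress and clock genes, noncoding RNAs and matrix.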

Results

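The data describe the RNA of 1 mouse heart, measured in 2 libraries made from poly(A) RNA at different times. Replicate 1 held 22775979 counts and replicate 2 held 19685806. After mitochondrial genes and their nuclear copies were set aside, 5028142 counts in replicate 1 and 12654709 in replicate 2 came from other nuclear genes. The libraries differed far beyond counting error, so the values of both are given and a mean ± SD covers technical spread only (n = 2 libraries).

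Mitochondrial RNA took a large share of both libraries, and the share was higher in replicate 1. The 13 mitochondrially encoded mRNAs and 2 rRNAs made up 65.0% of TPM in replicate 1 and 34.4% in replicate 2, a mean of 49.7% ± 21.6 (SD, n = 2). By counts the shares were 61.7% (95% Wilson interval 61.72 to 61.76) and 25.3% (25.23 to 25.27). These intervals cover counting error only, not the spread between libraries. The highest mean TPM were those of mt-Atp8, a subunit of ATP synthase, with 205490 and 103939, and mt-Co1, a subunit of cytochrome oxidase, with 106678 and 78034. The annotated transcript of mt-Atp8 is only 204 nt long (7766 to 7969) and overlaps that of mt-Atp6 (7927 to 8607). The counts of mt-Atp8, 249862 and 78735, were far below those of mt-Co1, 4698563 and 2047274. The first rank of mt-Atp8 therefore rests on the length correction of TPM for that short annotation. mt-Nd1 had 52261 and 32033 TPM, mt-Cytb had 45848 and 32502, and mt-Nd2 had 53862 and 23734. The rRNA mt-Rnr2 had 6815 and 4508 TPM, although the libraries were made from poly(A) RNA, and mt-Rnr1 had 3954 and 3320.

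A block of nuclear copies of 7 mitochondrial genes lies on chromosome 1, and each value of a gene or its copy is uncertain because the sequences are nearly identical. Of the counts of gene plus copy, the copies took from 0.52% (Gm29216) to 94.2% (Gm28438) in replicate 1 and from 0.012% (Gm28439) to 96.8% (Gm28438) in replicate 2. Of the 20 genes with the highest mean TPM, 11 were mitochondrially encoded, 7 were copies and 2 were other nuclear genes, Myl2 and Mb. Gm28661 (chromosome 1, 24614885 to 24615565), whose sequence is 100% identical to mt-Co2, had 76912 and 66688 TPM. Gm28439, a copy of mt-Nd4, had 224171 counts in replicate 1 and 66 in replicate 2, and Gm29216, a copy of mt-Co1, had 24381 and 263458. With the copies added, the mitochondrial share was 92.8% of TPM in replicate 1 and 60.9% in replicate 2, but 77.9% and 35.7% of counts. All other genes shared the remaining 7.22% and 39.1% of TPM, a 5.42-fold difference that enters every TPM of a nuclear gene. A limit of 1 TPM is therefore stricter for nuclear genes in replicate 1 than in replicate 2. Nuclear TPM denotes TPM rescaled without mitochondrial genes and copies.

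The contractile apparatus led the nuclear genes in replicate 2 and was far lower in replicate 1. Summed over the 26 sarcomere genes, TPM was 1715 in replicate 1 and 47945 in replicate 2 (nuclear TPM 23763 and 122632, 5.16-fold), and 21 of the 26 had at least 1 TPM in both. Myl2, the ventricular regulatory light chain (chromosome 5, 122100951 to 122113472), had 546 and 10108 TPM. Cardiac troponin T (Tnnt2) had 120 and 6078, tropomyosin Tpm1 had 345 and 5724, and cardiac actin Actc1 had 240 and 4224. The alpha myosin heavy chain gene Myh6 (chromosome 14, 54941921 to 54966927) had 39.7 and 4193 TPM. Myoglobin (Mb), which stores oxygen in muscle, had 154 and 8665.

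Genes of calcium handling summed to 3290 and 7904 TPM, but in nuclear TPM the sum was 2.25-fold higher in replicate 1, with 45576 and 20217. Phospholamban (Pln), the inhibitor of the calcium pump of the sarcoplasmic reticulum, had 2118 and 2361 TPM and was the highest gene of replicate 1 once mitochondrial genes and copies were set aside. The pump itself, Atp2a2, had 866 and 3319 TPM, S100a1 had 33.5 and 604, and the calcium-binding protein Hrc had 13.1 and 446. In nuclear TPM, Pln (29346 and 6039) and Atp2a2 (12003 and 8490) made up most of the sum. Gene by gene, 4 were called higher and 6 lower in replicate 2. Of 17 listed genes, 15 had at least 1 TPM in both libraries. Among 27 ion channel and gap junction genes, 11 did, led by connexin 43 (Gja1) with 75.6 and 138 TPM, Kcnip2 with 8.93 and 80.0, Kcnj3 with 36.8 and 34.3 and Abcc9 with 20.3 and 49.7.

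Fuel use was described by 3 lists. Of 25 genes of fatty acid oxidation, 22 had at least 1 TPM in both libraries, with a summed TPM of 2821 and 10442. In nuclear TPM that sum was 1.46-fold higher in replicate 1, with 39082 and 26709. Lpl (12469 and 3534 nuclear TPM), Hadhb (9285 and 2256) and Cd36 (5073 and 1133) weighed heavily in it. Gene by gene the direction was mostly the other way, with 12 called higher and 2 lower in replicate 2. Fabp3, the fatty acid binding protein of heart muscle, had 103 and 3136 TPM, lipoprotein lipase (Lpl) had 900 and 1382, Hadhb had 670 and 882, and the fatty acid transporter Cd36 had 366 and 443. The 19 glycolysis genes summed to 153 and 6937 TPM, a 45.5-fold difference between libraries that was 8.39-fold in nuclear TPM (2114 and 17744), and 15 had at least 1 TPM in both. Gapdh had 11.9 and 1568 TPM, Aldoa had 4.23 and 1257, Ldhb had 34.9 and 996 and Eno3 had 12.0 and 607. All 30 nuclear genes of the respiratory chain had at least 1 TPM in both libraries, with Atp5b at 200 and 2952, Ndufa4 at 511 and 1659, Cox6c at 355 and 1724 and the ADP/ATP carrier Slc25a4 at 156 and 1917.

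The 30 cytosolic ribosomal protein genes summed to 691 TPM in replicate 1 and 9621 in replicate 2 (nuclear TPM 9573 and 24608, 2.57-fold), and 24 had at least 1 TPM in both. Rps24 had 280 and 745 TPM, whereas Rplp1 had 2.90 and 845, Rps29 had 2.87 and 773 and Rps2 had 42.8 and 540. Of 22 cardiac transcription factors, 13 had at least 1 TPM in both. Mef2a had 30.6 and 40.2 TPM, Gata4 had 7.39 and 40.8, Mef2d had 2.07 and 41.7, and Esrra, an orphan nuclear receptor of energy metabolism, had 0.06 and 53.4.

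Markers of both chambers were present. Of 8 atrial markers, 7 had at least 1 TPM in both libraries, led by the natriuretic peptide Nppa with 37.2 and 2280, Myl7 with 7.11 and 851, Myl4 with 3.82 and 616 and sarcolipin (Sln) with 6.76 and 307. Of 5 ventricular markers, 4 did, with Myl3 at 12.6 and 3888, Irx4 at 0.08 and 9.65 and Irx3 at 1.07 and 4.83 beside Myl2. Conduction system markers were low, with 1 of 8 at 1 TPM in both, Gjc1 at 2.07 and 8.10, Tbx3 at 0.75 and 3.37, Cntn2 at 0.12 and 2.46 and Tbx18 at 0.85 and 1.34. Among 8 fetal and stress genes, 6 had at least 1 TPM in both, with Ankrd1 at 146 and 450, Nppb at 4.51 and 169 and skeletal actin Acta1 at 0.17 and 75.5.

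Markers of other cell types of the heart were also present. Of 16 endothelial markers, 11 had at least 1 TPM in both libraries (Ly6c1 9.71 and 119, Aqp1 2.25 and 112, Egfl7 2.52 and 101, Eng 0.59 and 54.3 TPM). Of 14 fibroblast markers, 11 did, with gelsolin (Gsn) at 3.98 and 506, decorin (Dcn) at 143 and 302, Mgp at 15.4 and 354 and Vim at 17.0 and 108. Of 12 mural cell markers, 4 did, with the pericyte gene Rgs5 at 101 and 126, smooth muscle actin Acta2 at 2.75 and 122 and Smtn at 0.30 and 76.6. Of 15 macrophage markers, 3 did, with Lyz2 at 11.5 and 102 and the complement genes C1qa, C1qb and C1qc at 0.25, 0.10 and 0.21 TPM in replicate 1 and 27.2, 26.6 and 24.2 in replicate 2. Red cell markers summed to 72.3 and 5027 TPM (nuclear TPM 1001 and 12858, 12.8-fold), and Hba-a2 had 17.9 and 1887 TPM, Hbb-bs had 49.8 and 1846, Hba-a1 had 0.25 and 933 and Hbb-bt had 3.99 and 347. The globin genes resemble each other closely, so the split between them is uncertain, and 2 listed symbols, Hbb-b1 and Hbb-b2, were not found in the tables.

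Lymphocyte markers reached at most 6.09 TPM (Ighm in replicate 2), with none of 10 at 1 TPM in both libraries, Cd79b at 0.03 and 0.72, Ms4a1 at 0.22 and 0.20 and Cd79a at 0 and 0.33. Among platelet markers Pf4 had 1.70 and 17.7 TPM, Ppbp had 0.55 and 0.64, Itga2b had 0 and 0.62 and Gp9 had no count. Epicardial and mesothelial markers included Upk3b at 0.36 and 11.7, Msln at 0.06 and 5.93, Aldh1a2 at 0.85 and 3.61 and Lrrn4 at 1.13 and 2.89 TPM. Schwann cell and neuron markers stayed under 1 TPM in replicate 1, with Cnp at 0.09 and 3.51, Dbh at 0 and 1.12 and S100b at 0.02 and 0.92. Of 5 lymphatic markers, 2 had at least 1 TPM in both, with Ccl21a at 0.14 and 20.8, Prox1 at 6.69 and 10.8, Lyve1 at 3.99 and 8.66 and Flt4 at 0.11 and 3.07.

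Neighbouring tissues left little or no RNA. Of the 6 lung markers, Sftpc, Sftpb, Sftpa1, Sftpd and Scgb1a1 had no count in either library, and Ager had 5 counts in replicate 2. A count of 0 allows up to 3 counts, a share of 1.32e-05% of replicate 1 and 1.52e-05% of replicate 2. The 4 thymus markers had at most 1 count, in Cd8b1 and Dntt in replicate 2, and Rag1 and Ptcra had none. Of 6 liver markers, Alb had 2.21 and 22.7 TPM, Cyp3a11 had 1.37 and 1.44, Apoa1 had 0.07 and 1.89 and Ttr had 0.03 and 1.71. Of 13 skeletal muscle markers, 1 had at least 1 TPM in both, Myl1 with 11.8 and 57.2, and Casq1, Mybpc2 and Tnni2 had 5.52, 5.22 and 3.42 in replicate 2. In this female mouse Xist, the RNA that silences an X chromosome, had 25.8 and 32.0 TPM, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had no count.

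Replicate 1 detected fewer genes, and its nuclear counts lay in genes of lower GC content, a mean of 45.04% against 50.51% in replicate 2. At 1 TPM or more it held 6274 genes and replicate 2 held 11772, of which 6222 were shared. Most of that gap came with the TPM scale, since at 1 nuclear TPM or more the libraries held 12144 and 13426 genes. Genes with any count numbered 15618 and 18108. The 100 most abundant genes took 94.9% of TPM in replicate 1 and 74.1% in replicate 2, the top 10 took 73.5% and 51.2%, and the top 1000 took 97.6% and 88.2%. With mitochondrial genes and copies set aside, the top 100 took 32.5% and 36.8%, and 38 of the 100 highest nuclear genes were shared.

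**Figure D1:**
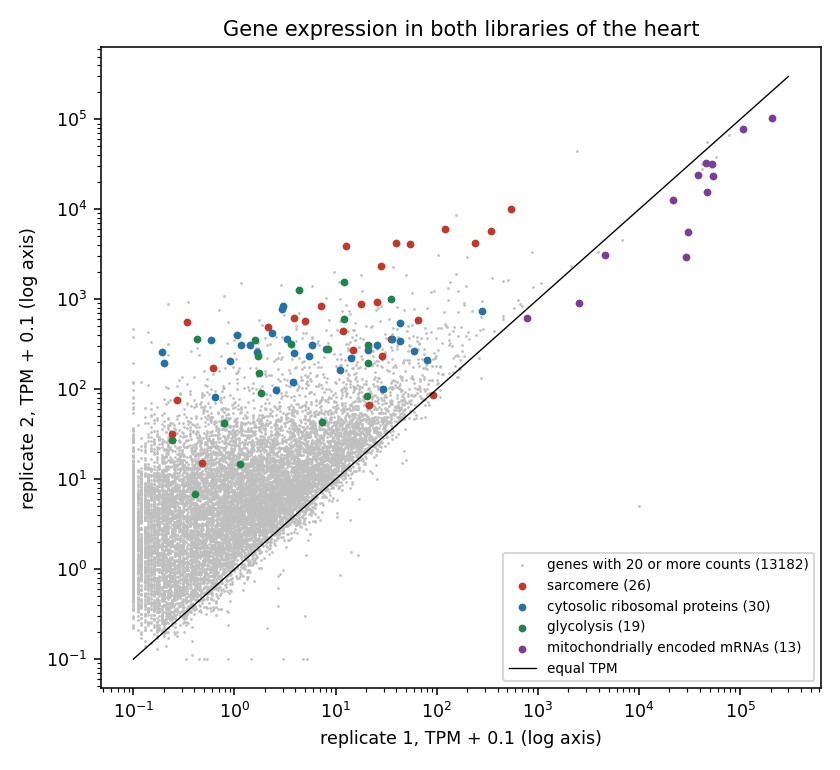
Each point is a gene, with its TPM + 0.1 in replicate 1 on the horizontal and in replicate 2 on the vertical log axis; colours mark 4 fixed gene lists and the line marks equal TPM. The summed TPM of the sarcomere genes was 1715 in replicate 1 and 47945 in replicate 2, and the mitochondrially encoded mRNAs summed to more in replicate 1.

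Ratios of related genes within a library compare the forms this heart used. With 0.1 TPM added to both genes, they depend on library scaling where a gene lies near 0. In 30 of 35 pairs the first gene was higher in both libraries (28 with replicate 1 adjusted to the GC profile of replicate 2). In 5 the sign differed between libraries. The 30 include near ties, such as Gata4 and Gata6 in replicate 1 (7.39 and 7.33 TPM) and Kcnj2 and Kcnj12 in replicate 2 (8.84 and 8.16 TPM). The adult ventricular myosin Myh6 exceeded the fetal form Myh7 by 82.9-fold in replicate 1 and 277-fold in replicate 2, a mean log2 ratio of 7.24 ± 1.23 (SD, n = 2). Mean log2 ratios were 7.80 ± 2.82 for Actc1 over Acta1, 8.45 ± 0.55 for Tnnt2 over Tnnt1, 7.91 ± 0.62 for Tpm1 over Tpm2 and 5.94 ± 0.29 for Casq2 over Casq1. Tnni1, the fetal troponin I, Ryr1 and Ckmt1 had no count in replicate 1 and 15, 5 and 17 counts in replicate 2. From counts per effective length, with a floor of 3 counts in the library, replicate 1 held at least 457-fold more Tnni3 than Tnni1, at least 4221-fold more Ryr2 than Ryr1 and at least 716-fold more Ckmt2 than Ckmt1. The lower limits of the 95% exact intervals in replicate 1 were smaller, at 371, 3432 and 582. The ratios in replicate 2 were 5070 (95% exact interval 3074 to 9060), 6419 (2750 to 19770) and 1764 (1102 to 3029). Atp2a1 had 1 and 59 counts, and Atp2a2 exceeded it 92439-fold (16591 to 3651160) in replicate 1 and 2072-fold (1607 to 2722) in replicate 2.

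Myl2 exceeded the atrial Myl7 by 4.91 ± 1.89 and Myl3 exceeded Myl4 by 2.18 ± 0.68 (log2, SD, n = 2). Among metabolic pairs, Eno3 exceeded Eno1 by 2.73 ± 0.01, Pfkm exceeded Pfkl by 4.25 ± 1.24, Slc25a4 exceeded Slc25a5 by 2.70 ± 0.96 and Ldhb exceeded Ldha by 1.23 ± 0.67. Ckm exceeded Ckb, which had 2 and 514 counts, 14.2-fold (95% exact interval 3.57 to 123) in replicate 1 and 52.4-fold (48.0 to 57.3) in replicate 2. The spread was wider than the mean for Cpt1b over Cpt1a (2.27 ± 2.83), while Slc2a4 over Slc2a1 gave 3.26 ± 1.67, Hk2 over Hk1 gave 2.84 ± 2.61, Cox8b over Cox8a gave 2.28 ± 1.63 and Fabp3 over Fabp4 gave 1.87 ± 1.65. The signs differed for Pgam2 over Pgam1 (−4.08 in replicate 1 and 3.09 in replicate 2), Cox6a2 over Cox6a1 (−0.42 and 3.70), Cox7a1 over Cox7a2 (−0.95 and 2.49), Esrra over Esrrb (−1.36 and 3.03) and Pdk4 over Pdk2 (4.45 and −0.48). Esrra had 2 counts in replicate 1, and its ratio to Esrrb from counts was 0.21 there (95% exact interval 0.024 to 0.79). For these 5 pairs the higher gene cannot be named from these libraries.

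Among regulators and channels, Mef2a over Mef2c gave 1.98 ± 0.07, Ppara over Pparg 1.01 ± 0.83, Gata4 over Gata6 0.59 ± 0.82, Gja1 over Gja5 5.60 ± 1.79, Kcnd2 over Kcnd3 0.79 ± 0.41 and Kcnj2 over Kcnj12 2.03 ± 2.72 (log2, SD, n = 2). Nppa over Nppb gave 3.38 ± 0.52 and Col3a1 over Col1a1 gave 2.77 ± 1.41. The GC trend between libraries was removed from pair ratios by adjusting replicate 1 to the GC profile of replicate 2. Such values take replicate 2 as the reference and keep any GC effect of that library. By that step Kcnj2 over Kcnj12 turned to −0.92, and in replicate 2 alone it was 0.11. Beyond the SD, that step moved Nppa over Nppb to 4.96, Col3a1 over Col1a1 to 1.10, Fabp3 over Fabp4 to 3.77, Tpm1 over Tpm2 to 6.60, Casq2 over Casq1 to 5.24, Kcnd2 over Kcnd3 to 0.09, Eno3 over Eno1 to 2.58 and Mef2a over Mef2c to 2.15. Within the wider SDs of other pairs it gave 1.30 for Hk2 over Hk1, 0.15 for Gata4 over Gata6, 1.58 for Ppara over Pparg, 6.91 for Actc1 over Acta1, 4.06 for Myl2 over Myl7, 4.74 for Gja1 over Gja5, 3.14 for Cpt1b over Cpt1a, 1.59 for Cox8b over Cox8a and 3.31 for Slc25a4 over Slc25a5. Posterior mean TPM gave 7.26 for Tnnt2 over Tnnt1, 0.29 for Kcnd2 over Kcnd3, 2.47 for Eno3 over Eno1 and 1.89 for Hk2 over Hk1. A pseudocount of 1 moved Tnnt2 over Tnnt1 to 7.62, Casq2 over Casq1 to 5.28, Eno3 over Eno1 to 2.49 and Mef2a over Mef2c to 1.88, beyond their SDs. Within the SD it gave 6.46 for Myh6 over Myh7, 6.74 for Actc1 over Acta1, 3.18 for Pfkm over Pfkl, 4.90 for Gja1 over Gja5, 2.64 for Slc2a4 over Slc2a1 and 1.34 for Kcnj2 over Kcnj12. Over the 35 pairs, the change of the ratio between libraries followed the difference in GC content of the pair's genes (Pearson r = 0.65, Spearman rho = 0.65, across pairs, which are not independent replicates).

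**Figure D2:**
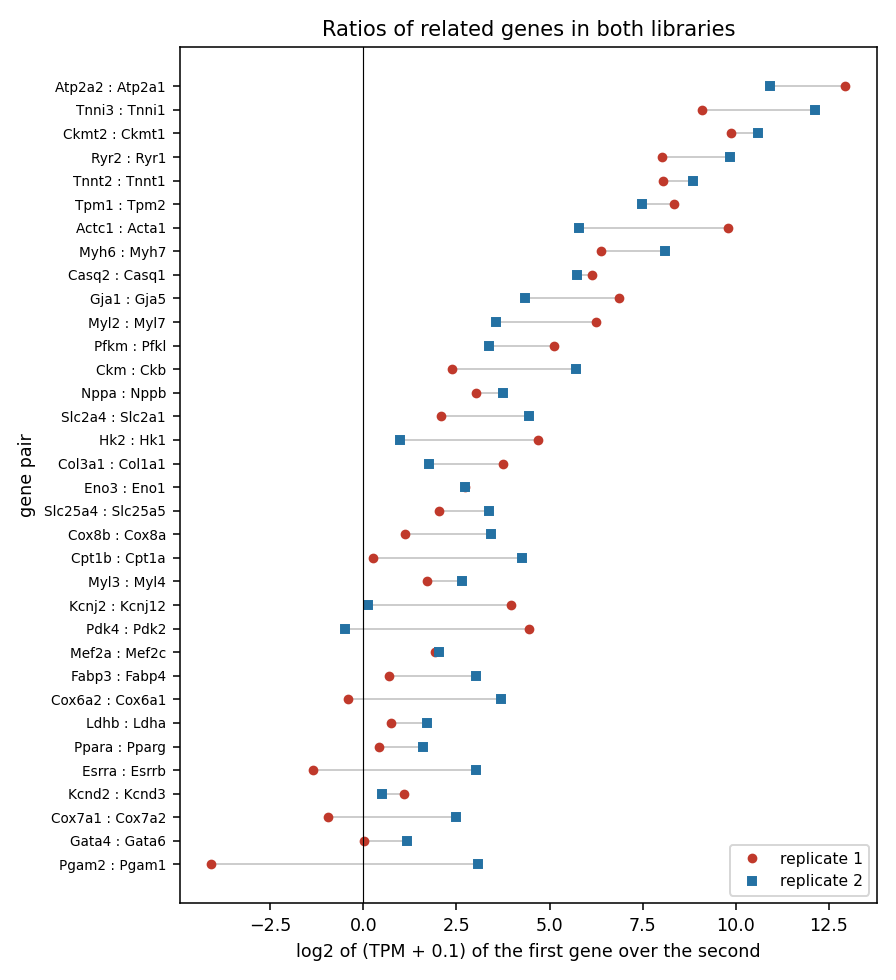
Each row is 1 of the 34 gene pairs drawn; the horizontal axis is log2 of (TPM + 0.1) of the first gene over the second, with a circle for replicate 1 and a square for replicate 2. Squares and circles lie on opposite sides of 0 in 5 of them, and the widest gap is that of Pgam2 and Pgam1, from −4.08 to 3.09; the circles of Tnni3, Ryr2 and Ckmt2 rest on the added 0.1 TPM, since their partners had no count in replicate 1.

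Isoform shares agreed for some cardiac genes and not for others. Of 25 fixed genes, 17 had the same leading transcript in both libraries. The 17 include Fhod3, which has only 1 annotated transcript and so could not differ. Titin (Ttn) was led by Ttn-201 with 76.3% and 77.7% of the gene's abundance, Tpm1 by Tpm1-205 with 94.3% and 96.9%, Atp2a2 by Atp2a2-202 with 94.9% and 95.4% and Pkm by Pkm-202 with 100% and 95.8%. Ryr2-201 took 79.2% and 99.2% and Mef2a-208 took 96.0% and 84.4%. The leading form changed for Tnnt2, where Tnnt2-201 took 56.1% in replicate 1 and Tnnt2-211 took 68.2% in replicate 2. It also changed for Ldb3 (Ldb3-202 with 94.0%, Ldb3-203 with 77.1%), Mef2c, Fhl1, Rbm20, Actn2, Vegfa and Myh6. Over 2562 genes with a mean TPM of at least 10 and more than 1 transcript, the leading transcript was the same in 60.7% (95% Wilson interval 58.8 to 62.6). That interval treats genes as independent, which they are not, and covers no spread between libraries. Where it differed, that of replicate 2 had the higher GC content in 82.3% of 977 genes.

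The 2 libraries of this heart were then compared gene by gene. Across 10766 genes with a mean TPM of at least 1, Pearson r of log2(TPM + 1) was 0.63 and Spearman rho 0.49; genes are not independent replicates. When these genes were divided into 5 equal groups by GC content, r was 0.95 in the lowest group and 0.61 in the highest. The chi-square over its degrees of freedom was 896 over 13182 genes, against about 1 for counting error alone, and the technical coefficient of variation was 98.6%.

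Of 13182 genes tested, 8642 differed between the libraries, 5075 higher and 3567 lower in replicate 2 (two-sided exact binomial test, edgeR, Benjamini-Hochberg adjusted). With library sizes set by total counts, 8669 genes were higher and 139 lower, so directions depend on the scaling. The median log2 ratio of all genes was 0.23 with TMM, 0.12 with median-of-ratios factors and 1.89 with total counts, and the changes of named genes and lists are given relative to the median gene where stated. The difference has no replicate check.

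Genes highest in replicate 2 included ribosomal and respiratory genes with next to no count in replicate 1. Rps15 had 0 and 2823 counts, at least 340-fold higher in replicate 2 after TMM scaling, with a floor of 3 counts per library, and Rpl36 (0 and 1601 counts) and Fau (0 and 1475) were at least 193-fold and 177-fold higher. The lower limits of the 95% exact intervals of these 3 genes were smaller, at 276, 156 and 144. Atp5d, a subunit of ATP synthase, had 1 and 6169 counts, a ratio of 2227 (95% exact interval 400 to 87964), and Uqcr11 had 1 and 4430, a ratio of 1599 (287 to 63172). Oplah, Gga1, Mbd3, Rnh1 and the unnamed ENSMUSG00000103888.1 completed the 10, each with no count in replicate 1. With the floor of 3 counts each was at least 92.4-fold higher, and by the exact intervals at least 75.0-fold. Those lowest in replicate 2 were mostly pseudogenes, whose reads are uncertain. They were Gm28439, Gm4294, Gm12978, Gm29397, Gm9762, Gm7206, Gm12693 and Gm7329, together with mt-Co2, with 465877 and 28511 counts, and Kap, with 27 and 1. The counts of mt-Co2 are uncertain too, since its copy Gm28661 took 72.6% of gene plus copy in replicate 1 and 95.7% in replicate 2. From unscaled counts, the log2 ratio was −4.03 for mt-Co2 and −1.36 for gene plus copy.

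The ratio between libraries followed GC content more closely than any other property examined. Spearman rho of the log2 ratio with GC content was 0.90 across 13155 genes, against −0.29 with transcript length and 0.02 with mean TPM. In the lowest of 10 equal groups by GC content, up to 41.8%, the median log2 ratio was −2.03, and in the highest, from 57.9%, it was 4.94. The median TPM of that highest group was 0.05 in replicate 1 and 6.43 in replicate 2, and that of the lowest was 3.71 and 4.19. Relative to the median gene, Myl2, with 51.7% GC, had a log2 ratio of 2.36 and Myh6, with 56.4%, had 4.76, while Pln, with 38.6%, had −2.29. With the GC trend removed, 2758 genes were called, 1292 higher and 1466 lower in replicate 2, and 1954 of them were also among the 8642, 1453 in the same direction and 501 in the opposite one. The technical coefficient of variation was then 45.4% over the genes that kept at least 20 counts after that step, against 87.3% for the same genes before it.

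**Figure D3:**
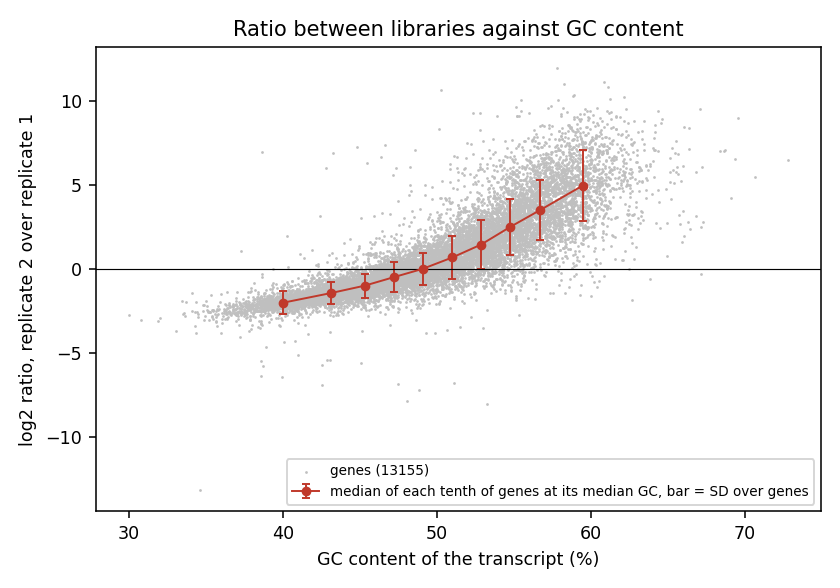
Each point is a gene, with the GC content of its transcripts in percent on the horizontal axis and the log2 ratio of replicate 2 over replicate 1 on the vertical; circles are medians of 10 equal groups of genes by GC content and bars are SDs over genes. The medians run from −2.03 at the lowest GC content to 4.94 at the highest.

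Among 29 fixed lists with enough tested genes, 7 had a median outside the central 95% of random lists. Counts of called genes adjusted over the list alone were equal to those over all genes for all 37 lists. Relative to the median gene, 5 lists were higher in replicate 2. These were glycolysis (median log2 3.80, percentile 100, 17 of 19 genes called higher), ribosomal proteins (3.37, percentile 99.99, 25 of 30), the sarcomere (3.19, percentile 99.9, 21 higher and 1 lower of 26), mural cell markers (2.96, percentile 99.5) and endothelial markers (1.95, percentile 97.9). The mitochondrially encoded mRNAs had −3.24, with 13 of 13 called lower, and nuclear long noncoding RNAs had −2.08 at percentile 0.37, with Malat1 at 273 and 132 TPM, Neat1 at 66.8 and 320 and Meg3 at 0.69 and 12.96 beside Xist.

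With the GC trend removed, 14 lists lay outside, 7 on each side. Above were ribosomal proteins (2.10), red cell markers (2.70), glycolysis (1.53), the sarcomere (1.45), adipocyte markers (1.44), atrial markers (1.43) and mural cell markers (0.75). Below were immediate early genes (−1.02), conduction system markers (−0.91), epicardial and mesothelial markers (−0.70), mitochondrially encoded mRNAs (−0.69), extracellular matrix (−0.66), cardiac transcription factors (−0.42) and ion channels (−0.35). Relative to the median gene before that step, immediate early genes (1.35), ion channels (1.33), cardiac transcription factors (0.78) and extracellular matrix (0.67) were higher in replicate 2. Their sign turned only with the correction. Conduction system markers (−0.70), epicardial and mesothelial markers (−0.35) and mitochondrially encoded mRNAs (−3.24) were lower before it too. Extracellular matrix genes, led by Dcn, Sparc (12.4 and 103 TPM), Bgn (12.7 and 89.1) and Timp3 (26.2 and 48.8), had 0.67 relative to the median gene before the trend was removed.

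**Figure D4:**
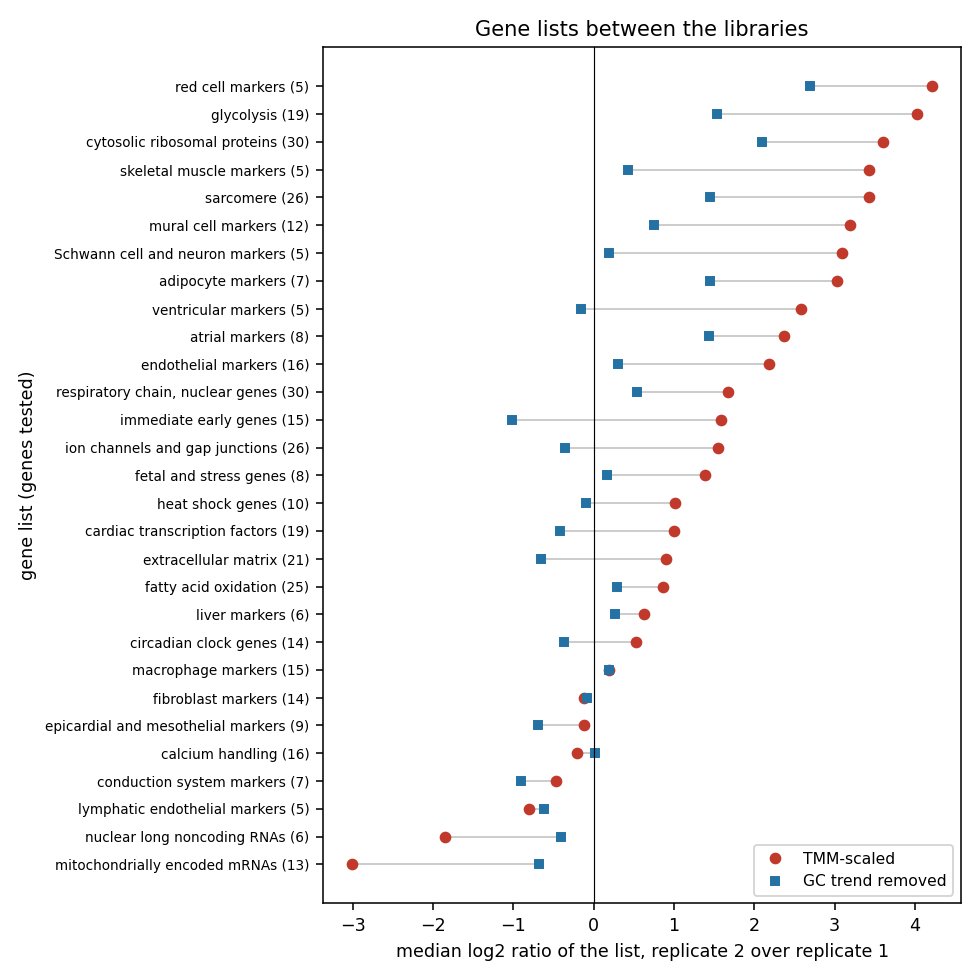
Each row is a fixed gene list with its number of tested genes; the horizontal axis is the median log2 ratio of replicate 2 over replicate 1, with a circle for TMM scaling and a square after the GC trend was removed. The median of ribosomal proteins falls from 3.60 to 2.10 with that step, and that of immediate early genes moves from 1.58 to −1.02.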

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

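The GC correction, the removal of nuclear copies, total counts without mitochondrial genes, pair ratios without a pseudocount and noise over the genes kept were chosen after seeing the data; a correlation counted as moved beyond 0.05, a trend beyond 0.1 and a count beyond 1.5 times. Between 6886 (100 counts or more) and 10205 (1.5-fold) genes were called under the other scalings, filters, error models and gene sets, against 2758 with the GC trend removed (1292 higher and 1466 lower in replicate 2); total counts gave 8669 higher and 139 lower. Pearson r was 0.56 with a pseudocount of 0.1, 0.81 with no filter, 0.46 at a mean TPM of 10 or more and 0.82 with the GC trend removed, and Spearman rho was 0.88, 0.55, 0.22 and 0.79 with no filter, posterior mean TPM, a mean TPM of 10 or more and the GC trend removed. The chi-square over its degrees of freedom was 474 without mitochondrial genes and 289 with the GC trend removed. That step rescaled counts of replicate 2, lowering those of GC-rich genes and raising those of genes with low GC content. It also removed genes, so 289 is no measure against counting error alone. For the genes kept, the uncorrected value was 1010. Their technical coefficient of variation was 45.4%, against 87.3% uncorrected. Otherwise the cause was not tested. Lists outside the central 95% numbered 14 with the GC trend removed. List entries count a gene once in each list that holds it. They numbered 173 at 5 TPM or more in both libraries, a stricter limit, against 266 at 1 TPM. The mean mitochondrial share was 76.8% with copies added and the mean share of the top 100 genes 34.6% without mitochondrial genes and copies, by construction.

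Leaving out 1 library gave a mitochondrial share of 34.4% to 65.0% and a top 100 share of 74.1% to 94.9%. It gave 6274 to 11772 genes at 1 TPM, 266 to 394 list entries and 31 to 34 pairs led by the first gene. Ratios that changed sign were Pgam2 over Pgam1 (0.22 with a pseudocount of 1, −4.08 to 3.09 over the libraries, 0.40 with the GC trend removed), Pdk4 over Pdk2 (−0.48 to 4.45 over the libraries, −0.29 with the GC trend removed), Kcnj2 over Kcnj12 (−0.92 with the GC trend removed) and, over the libraries, Cox6a2 over Cox6a1 (−0.42 to 3.70), Cox7a1 over Cox7a2 (−0.95 to 2.49) and Esrra over Esrrb (−1.36 to 3.03); the cause was not tested. No paired analysis was possible because there is 1 animal and no group to compare. Under alternatives that kept both libraries, 180 pair ratios stayed within the SD of the main value and 26 moved beyond it, and 83 counts per list stayed within 1.5 times and 28 did not, while 3 TPM values stayed within the SD and 6 did not; 1 of 2 libraries always lies within 1 SD of their mean, so that comparison was not made. Ryr2 over Ryr1 ran from 5.75 to 11.58 over pseudocounts of 1 and 0.01, and posterior mean TPM gave 8.88 for Tnni3 over Tnni1, 8.18 for Ckmt2 over Ckmt1 and 10.75 for Atp2a2 over Atp2a1, against 10.61, 10.23 and 11.94 with 0.1 TPM added. Nuclear counts were 2.52 times fewer in replicate 1, which limits low genes there; 208 genes with at least 100 counts in replicate 2 had none in replicate 1, and their median GC content was 59.3%, against 50.04% over genes tested.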

Other observations

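Genes that respond to handling, stress and time of day were also measured. Of 16 immediate early genes, 7 had at least 1 TPM in both libraries, with Dusp1 at 4.71 and 37.7 TPM, Ccn1 at 2.14 and 29.8, Nr4a1 at 0.59 and 19.6 and Ier3 at 0.82 and 19.4. Of 10 heat shock genes, 6 did, led by Hspa8 with 119 and 727, Hspb6 with 70.5 and 368, Hspb7 with 1.90 and 376 and Hspb8 with 15.1 and 236. Clock genes included Tef at 3.72 and 33.0, Nr1d2 at 16.2 and 17.9, Nr1d1 at 0.27 and 16.8 and Clock at 6.19 and 9.09. Of 10 cell cycle genes, 8 were below 1 TPM in both libraries, and Pcna, which also serves DNA repair, had 9.98 and 23.3.

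Markers of fat and RNAs without a poly(A) tail were also measured. Among 8 adipocyte markers, Fabp4 had 63.2 and 383 TPM, Cfd had 0.08 and 24.4, Adipoq had 1.26 and 8.29, and Ucp1, the uncoupling protein of brown fat, had 1.52 and 13.04. Endothelial cells also express Fabp4, whose log2 ratio was −0.14 relative to the median gene, and the median of the adipocyte list lay at percentile 95.5 of random lists, or 61.7 at 100 counts or more. Of 10 RNAs without a poly(A) tail, 4 had no count and Hist1h1c had 4.90 and 66.3 TPM, with Rn7sk, Hist1h1e and Rpph1 at 0 in replicate 1 and 2.12, 1.40 and 0.38 in replicate 2.

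The design gives no groups, so apart from the share of heart chambers no biological explanation was tested for the patterns that follow. The tests on the spread of nuclear ratios and on copies, and the comparisons with random lists of atrial and ventricular markers, were chosen only after the result was seen. GC-rich genes such as Myh6 and Gapdh had far fewer counts in replicate 1. A larger share of mitochondrial RNA would lower all nuclear genes by 1 factor, but their log2 ratios had an SD of 2.51, and transcript length at equal GC content gave a partial rho of only −0.25, against 0.90 for GC content at equal length. Loss of fragments by GC content predicts that AT-rich stretches rescue a transcript, and at equal mean GC the lowest GC of any 200-nt window had a partial rho of 0.37 with the ratio. Ribosomal protein genes spread 3.20 times as widely (SD of log2 TPM) in replicate 1 as in replicate 2, and their TPM followed GC content there (rho −0.64, against 0.15 in replicate 2), so the distortion may lie mainly in replicate 1; the step that made it stays open.

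After the GC trend was removed, 2758 genes were called, 1453 of them in the same direction as before. Among the 2735 with a GC value, the corrected ratio fell with the share of windows under 45% GC (rho −0.32), which is consistent with AT-rich stretches keeping GC-rich genes in replicate 1; Arf6 (60.0% GC, 603 and 535 counts) and Gas1 (58.4%, 386 and 394), chosen after their values were seen, are examples. A different share of chambers in the RNA stays open too. Atrial markers had a median corrected log2 ratio 1.59 above ventricular markers, a gap that 2.32% of random lists matched on expression and 4.84% of those matched on GC content reached, but members ranged from −4.91 to 3.85 over 8 atrial and from −5.74 to 3.26 over 5 ventricular genes. Before the correction, the median log2 ratio was 2.37 for atrial and 2.58 for ventricular markers, so atrial markers were not the higher ones. The gap of 1.59 appeared only with the correction, and the ventricular minimum, Irx3, has 62.5% GC. The test therefore cannot separate a difference in chambers from an effect of the correction itself.

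Mitochondrial genes and their chromosome 1 copies held different shares of their joint counts in the libraries. Over 7 genes with a copy, log2 ratios of gene plus copy had an SD of 0.27 and those of the copies alone 4.64, a quotient of 0.057. The spread of the copies rests on Gm28439 (−11.72) and Gm29216 (3.43), which held at most 13.1% and 11.4% of gene plus copy, so the quotient follows from their small share and decides nothing. The other 5 copies ran from −1.36 to −0.49, with an SD of 0.35 against 0.25 for gene plus copy and 1.03 for the mitochondrial genes alone. Whether reads were split between near-identical sequences in ways that differ by library stays open.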
